A study of Mus musculus with 12 samples.

How the data were processed

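RNA sequencing libraries from 12 cultures were analysed, 3 in each of 4 groups. The cells are mouse embryonic fibroblasts immortalised with SV40 large T antigen and deficient in Fadd and Mlkl or in Casp8 and Mlkl, each transduced with an empty vector or with the missing Fadd or Casp8. RNA came from untreated cells 24 h after plating. Per the labels, libraries were made from total RNA with a stranded kit, reads were trimmed with Cutadapt in Trim Galore 0.5.0, aligned with STAR 2.7.5a to mouse genome mm10 with a GENCODE M22 annotation, and counted per gene with RSEM. The deposited gene tables hold 3 values per gene per the file headers, which are RSEM expected counts, TPM and the length-scaled fragment unit FPKM. The expected counts were used here, and the TPM and FPKM columns were not used here. Of the counts above 0, 96.05% are whole numbers exactly, and the values carry no normalisation. A further deposited table holds expected counts for annotated endogenous retrovirus open reading frames, 1 column per library, named by genome position. Every value in it is a multiple of 0.5, and 46.7% of those above 0 were not whole numbers; how its reads were counted, and how reads mapping to several places were shared, is not given in the sources used here. The labels also name HOMER 4.11, Picard, SAMtools and DESeq2 without a role for these tables.

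Each gene table has 55665 rows, of which 92 are spike-in controls with 0 counts that were left out. Gene positions and biotypes came from GENCODE M21 on the same genome, since M22 was not at hand. It matched 55480 of 55573 gene identifiers and 16392 of the 16396 genes tested. Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with a minimum count of 10, and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 12 libraries in edgeR 4.0.16 (R 4.3.3), with a common biological coefficient of variation of 0.37. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and genes with an adjusted p under 0.05 are called. Standard errors were derived from the fitted change and its F statistic, and are not given where a group has no counts. Depth ranged from 33918359 to 59388559 counts per library. Folds against a group with no counts are lower bounds against 3 counts over the group, and ratios against 1 to 3 counts carry a 95% counting interval.

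The comparisons were knockout against put back in each line, the difference between those changes, the genes changed the same way in both lines, and the knockout groups against each other. In all, 16 gene lists were tested in the first 3 contrasts (48 tests, adjusted together) with camera in limma 3.58.1, using a preset correlation between genes of 0.01. The same tests were repeated with an estimated correlation and with fry. The lists cover cell death, type I interferon response, antigen presentation with interferon gamma response, nucleic acid sensing, interferons and receptors, NF-kappaB and inflammation, p53 targets, stress of the endoplasmic reticulum, cell cycle, extracellular matrix, retroelement silencing, and leukocyte, epithelial, endothelial, muscle and neural markers. List members were also counted with p-values adjusted over the list alone. Retrovirus regions were tested in the same way with library sizes and TMM factors of the gene tables, after rounding to whole counts, and their totals as CPM of the gene counts were compared with exact permutation tests. Exact paired tests, which flip the sign of each pair's difference, were added after the data were seen. No family names are in that table, so totals by family were not analysed here.

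Groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule takes Fadd, Casp8, Mlkl, Zbp1, Ripk1 and Ripk3, then per line the 5 largest rises and 5 largest falls among called protein-coding genes with at least 5 CPM in the higher group and no overlap between groups, and up to 4 called members per list. It also takes the 4 highest and 4 lowest for the difference between lines, and the 3 highest and 3 lowest between the knockout groups. For genes changed in both lines it named none, and for retrovirus regions it asked for a mean of 50 counts, which no called region reached. Members of lists that did not pass are named to show values and were chosen after their values were seen.

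Libraries with the same replicate number deviated together within each line. The correlations of their deviations from the group means were 0.66, 0.391 and 0.639 in the Fadd line and 0.203, 0.305 and 0.127 in the Casp8 line, all above 0.1, so the numbers were read as pairs within a line. Across the knockout groups of both lines the values were -0.252, 0.0711 and -0.371. The labels do not say what a number marks. The planned block used the replicate number over all 12 libraries, and a block within each line was added after this check. The first principal component held 52.3% of the variance and the second 14.5%.

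The alternatives were DESeq2 size factors within edgeR, no count filter, a minimum of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the compared libraries alone, the replicate blocks, a change of at least 2-fold, and each library left out in turn. For the retrovirus table its own scaling, effective library sizes and totals without the 10 most abundant regions were tried. The DESeq2 size factors moved the median change of all genes by at most 0.0217 on the log2 scale. Leaving out both replicate 1 libraries of the Casp8 line, or of the Fadd line, was added after the data were seen.

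The pipeline was tested on simulated data built on these libraries' depths and spread. In the Fadd line it recovered 20% of genes changed 2-fold, 64% at 4-fold, 94% at 8-fold and 96% at 16-fold, and in the Casp8 line 10%, 80%, 90% and 96%. For the difference between lines the shares were 2%, 52%, 84% and 90%, so a 2-fold difference was rarely detectable. Calls among unchanged genes numbered 1 in the Fadd line, 11 in the Casp8 line and 2 for the difference. The changed genes had at least 1 CPM, and libraries were drawn without the pairing seen in the real data. The real libraries may therefore allow lower shares. With no change simulated, 0 genes were called in either line and 0 lists. Genes were drawn independently of each other there, so the 0 lists do not test camera's preset correlation. In the real data the estimated correlation of the type I interferon list was 0.744 in the Fadd line.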

Results

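RNA was sequenced from 12 cultures of immortalised mouse embryonic fibroblasts, in 4 groups of 3 cultures, which the labels call independent. Cells labelled as knocked out for Fadd and Mlkl carried an empty vector or Fadd put back, and are called the Fadd line here. Cells labelled as knocked out for Casp8 and Mlkl carried an empty vector or Casp8 put back, and are called the Casp8 line. FADD is the adaptor that brings caspase-8 to death receptors, caspase-8 is a protease that starts apoptosis and restrains necroptosis, and MLKL is the protein that carries out necroptosis. The cells were untreated and harvested 24 h after plating. Total expected counts were 54731635, 53706992 and 45936607 in the Fadd/Mlkl knockout libraries and 43774047, 39848303 and 46272072 after Fadd was put back. The Casp8/Mlkl knockout libraries held 45047945, 45421189 and 33918359 counts, and those with Casp8 put back 50922210, 59388559 and 50439711. Levels below are CPM, counts scaled by library size, as mean ± SD with n = 3 libraries per group, and changes are log2 ratios of knockout over put back, with the standard error (SE) of the edgeR fit. A positive change means a higher level without the protein. The study's title names Zbp1, a sensor of nucleic acids that can trigger necroptosis, so the comparisons ask which genes, Zbp1 among them, differ when FADD or caspase-8 is absent.

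More genes were called lower than higher without FADD in the Fadd line, against cells with Fadd put back. Fadd itself (ENSMUSG00000031077.7, mm10 chromosome 7, 144577318 to 144582463) fell from 23.65 ± 3.96 to 0.0999 ± 0.0704 CPM, a log2 change of -7.84 (SE 0.44, adjusted p = 1.32e-05). In all, 203 genes fell and 47 rose, of which 192 and 40 changed at least 2-fold, by edgeR at an adjusted p under 0.05 over 16396 genes. At an unadjusted p under 0.05 there were 1682 genes (721 higher, 961 lower), against 819.8 by chance, and DESeq2 called 224 higher and 473 lower. The count was 444 with a replicate block within each line (106 higher, 338 lower). It was 144, 125 and 103 without knockout replicate 1, 2 or 3, and 135 without put-back replicate 2.

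The largest falls were in genes that were close to silent without FADD. Gas6, a ligand of the TAM receptor kinases (ENSMUSG00000031451.6, chromosome 8, 13465374 to 13494490), had no reads in the 3 knockout libraries and 8.517 ± 4.112 CPM with Fadd put back. That is at least 451-fold lower against a floor of 3 counts over the group (adjusted p = 0.000493). Zfp422, a zinc finger gene (ENSMUSG00000059878.12, chromosome 6, 116624016 to 116628999), had 1 count over the knockout libraries against 15.01 ± 1.37 CPM, a ratio of 2360 with a 95% counting interval of 423 to 93200. Enpp5 (ENSMUSG00000023960.13, chromosome 17, 44078813 to 44086567) also had 1 count without FADD, against 9.21 ± 4.25 CPM, a ratio of 1460 (261 to 57700). Cadm1, a cell adhesion molecule (ENSMUSG00000032076.19, chromosome 9, 47530173 to 47857637), fell by 10.32 on the log2 scale (SE 1.61) from 84.4 ± 31.7 CPM. Its adjusted p of 0.00804 became 0.0514 without knockout replicate 2 and 0.0561 without knockout replicate 3. Fbln2, which codes for the matrix protein fibulin 2 (ENSMUSG00000064080.12, chromosome 6, 91212455 to 91272540), fell by 10.15 (SE 1.07, adjusted p = 0.000668; 0.0749 with limma-voom). These intervals and floors cover counting error alone.

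Among the genes that rose without FADD, Hoxc11, a homeobox transcription factor gene (ENSMUSG00000001656.3, chromosome 15, 102954427 to 102957708), stood at 8.49 ± 1.99 CPM and had no reads in the 3 libraries with Fadd put back. That is at least 375-fold higher (adjusted p = 1.35e-05). Negr1, a neuronal adhesion gene (ENSMUSG00000040037.13, chromosome 3, 156561794 to 157316445), rose by a log2 of 6.84 (SE 1.05, adjusted p = 0.00736), from 7 counts over the put-back group. Klhl38 (ENSMUSG00000022357.2, chromosome 15, 58314573 to 58324169) rose by 5.34 (SE 1.09, adjusted p = 0.0358), and its adjusted p ran from 0.0538 to 0.179 when any library other than knockout replicate 3 was left out. Oasl1, an interferon-induced gene (ENSMUSG00000041827.15, chromosome 5, 114923240 to 114937915), rose by 3.94 (SE 0.63, adjusted p = 0.00917), from 1.86 ± 0.81 to 28.6 ± 26.4 CPM. Its adjusted p was 0.06 with the replicate block within each line and 0.0823 when only the 6 libraries of the line were fitted. Reads assigned to Olfr56 (ENSMUSG00000040328.15, chromosome 11, 48978889 to 49135387) rose by 4.12 (SE 0.786, adjusted p = 0.0265). This annotated span contains Ifi47, an interferon-induced GTPase gene on the same strand, whose reads rose by 3.48 (SE 0.579, adjusted p = 0.0114), so the source of the Olfr56 reads is uncertain. Ifi47 was named after its values were seen. The Olfr56 call was lost without knockout replicate 1 (adjusted p = 0.0846) or 2 (0.0556), without put-back replicate 1 (0.0935) or 3 (0.108), and with the block within each line (0.0674).

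**Figure D1:**
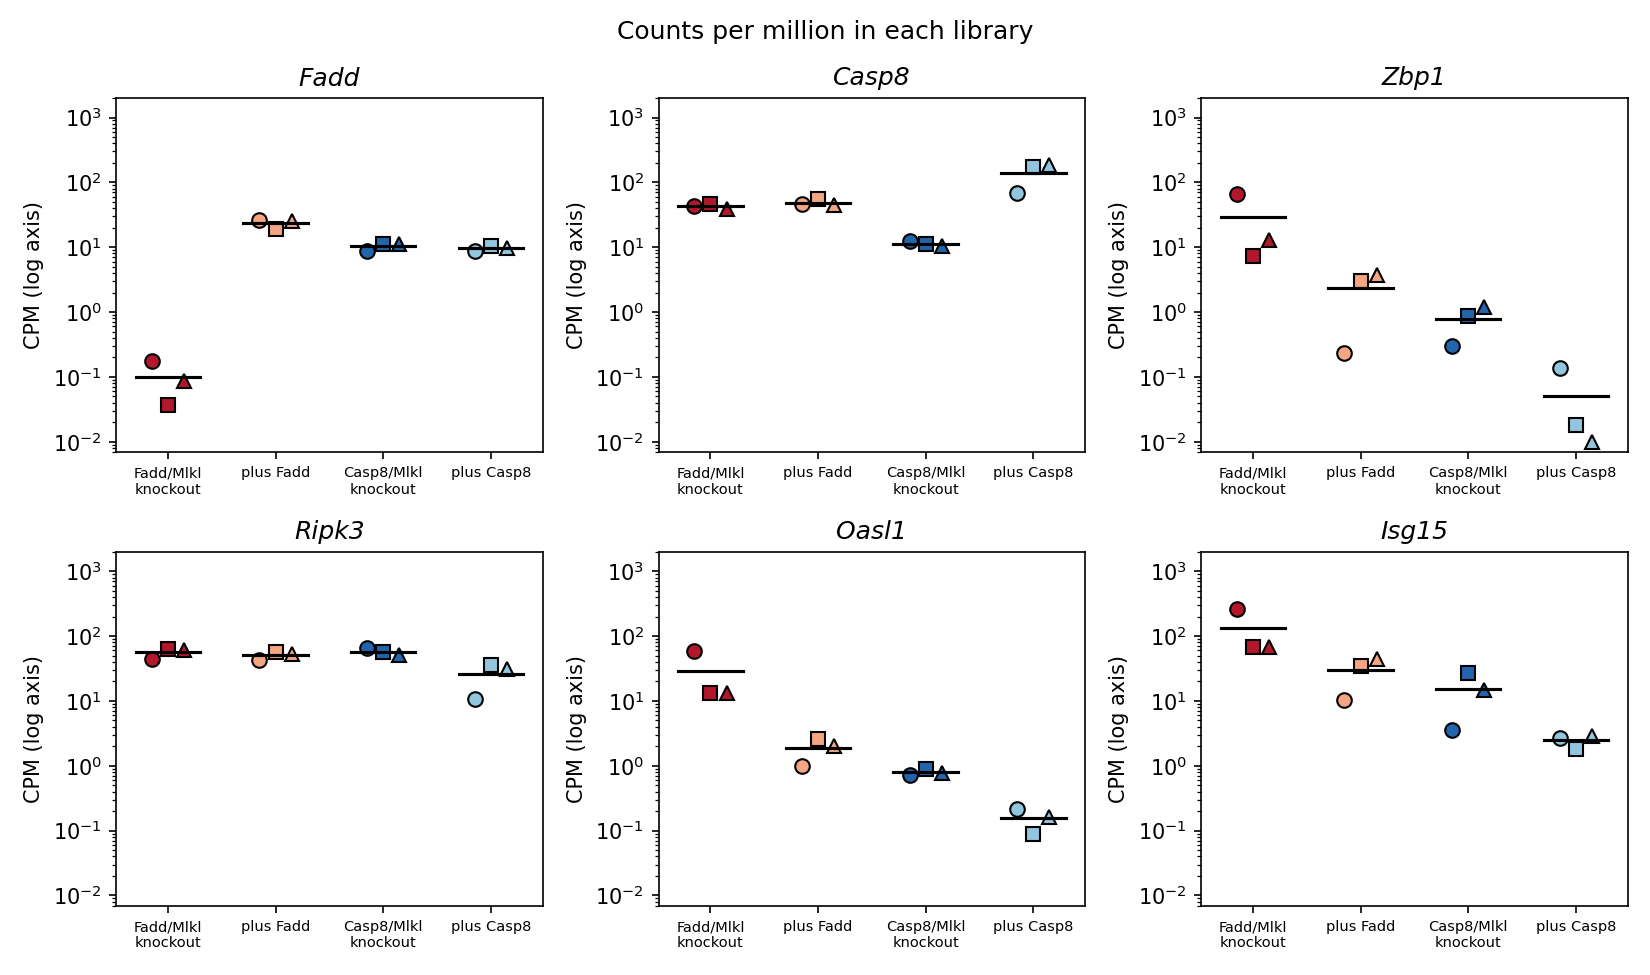
Levels of 6 genes in CPM on a log axis, for each of the 12 libraries in the 4 groups. Circles, squares and triangles are replicates 1, 2 and 3, lines are group means, and values under 0.01 are drawn at 0.01. Fadd and Casp8 are lowest in the line that lacks them, and Zbp1 ranges from 7.28 to 66.1 CPM in the Fadd/Mlkl knockout libraries.

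Zbp1 (ENSMUSG00000027514.14, chromosome 2, 173206612 to 173218923) was at 28.8 ± 32.4 CPM without FADD and 2.33 ± 1.86 CPM with Fadd put back, a log2 change of 3.63 (SE 1.1) that did not pass over all genes (edgeR adjusted p = 0.189). All 3 knockout libraries (66.1, 7.28 and 13 CPM) lay above all 3 put-back libraries (0.235, 2.99 and 3.78 CPM). Adjusted over the list alone, Zbp1 passed among the 25 tested members of the cell death list (edgeR adjusted p = 0.0435). Without knockout replicate 1 the log2 change was 2.12 (adjusted p = 0.563). The other genes of the necroptosis pathway had log2 changes of 0.15 for Ripk3, 0.14 for Ripk1 and -0.32 for Mlkl (adjusted p = 1, 0.952 and 0.975). The sign for Mlkl turned to 0.13 without put-back replicate 1. Mlkl transcripts were present in all groups, at 8.50 ± 2.82 and 10.62 ± 4.56 CPM in the Fadd line and 7.49 ± 3.29 and 6.37 ± 0.96 CPM in the Casp8 line (knockout, then put back), and transcript levels do not show whether protein is made.

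The type I interferon response list had a positive median change in this line, which rests on camera's preset correlation and was not called with an estimated one or with fry. The median log2 change over its 55 tested members was 2.16, with 54 members above 0. With 1 library of the line left out it ran from 1.19 to 2.69, and it was 0.78 without both replicate 1 libraries, a setting chosen after seeing the data. Knockout replicate 1, with the highest mean of this list (7.09 against 5.27 and 5.38), also had the lowest protein-coding share of all libraries (81.4% against 85.0 to 88.8%) and the highest share of ribosomal RNA (0.108%). Over all genes 1 member passed with edgeR (Oasl1), against 18 with DESeq2, 2 with limma-voom and 0 with the block within each line, and 41 rose adjusted over the list alone. Isg15, a ubiquitin-like modifier, stood at 133 ± 113 against 29.9 ± 17.8 CPM (log2 2.16, adjusted p = 0.293), and the transcription factor gene Irf7 at 188 ± 227 against 20.3 ± 6.2 CPM (log2 3.21, adjusted p = 0.192). Oas2 and Oas3, which code for sensors of double-stranded RNA, had log2 changes of 4.80 and 4.36 (adjusted p = 0.0547 and 0.0865). Among the 37 members of the antigen presentation and interferon gamma list, all 37 were higher, with a median of 2.11 (1.18 to 2.46 with 1 library left out, 0.92 without both replicate 1 libraries), but 0 passed over all genes with edgeR and 25 rose adjusted over the list alone. There were 28 at an unadjusted p under 0.05, 16 with DESeq2, 1 with the block within each line and 0 with limma-voom. The class I gene H2-K1 was at 1254 ± 906 against 323 ± 117 CPM (log2 1.96, adjusted p = 0.167) and the peptide transporter gene Tap1 at 122 ± 90 against 32.1 ± 9.9 CPM (log2 1.92, adjusted p = 0.175). Reads of the H2, Oas and Ifit families may be shared between close relatives. The mean log2 CPM over the type I interferon list was 5.91 ± 1.02 without FADD and 3.69 ± 1.07 with it, and an exact permutation test gave p = 0.1, the smallest that 3 against 3 allows (two-sided). All 3 pairs of the same replicate number differed this way (exact paired permutation p = 0.25, the smallest for 3 pairs).

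By limma's camera with a preset correlation of 0.01, 6 of the 16 lists shifted in the Fadd line, and 0 did with an estimated correlation or with fry. The lists that ranked high were type I interferon (adjusted p = 3.28e-31), antigen presentation (8.82e-22), NF-kappaB and inflammation (median 0.69, 6.12e-06) and nucleic acid sensing (median 0.23, 0.00342). With an estimated correlation their adjusted p were 0.231, 0.231, 0.231 and 0.516. The sensing list shares Ifih1, Ddx58, Dhx58, Zbp1, Adar and Eif2ak2 with the type I interferon list, so these calls are not independent. Relb, an NF-kappaB subunit gene, rose by 0.92 (SE 0.184, adjusted p = 0.0338). The Relb call was lost when any library other than knockout replicate 2 was left out (adjusted p from 0.0621 to 0.159) and with the block within each line (0.0643). In the NF-kappaB list 1 of 25 members rose over all genes (DESeq2 4, limma-voom 1, and 1 beside 1 that fell with the block within each line) and 4 rose adjusted over the list alone, while in the sensing list 0 of 21 passed with edgeR (9 at an unadjusted p under 0.05; DESeq2 1 higher and 1 lower; limma-voom 0) and 2 rose and 1 fell adjusted over the list alone. The sensing list was lost without knockout replicate 1 (adjusted p = 0.289) and with the block within each line (0.0516).

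The lists that ranked low without FADD were the extracellular matrix and fibroblast genes (median -0.66, adjusted p = 9.75e-08) and the p53 targets (median -0.14, adjusted p = 0.0387), with 0.231 and 0.653 as adjusted p with an estimated correlation. Of 35 matrix genes, 3 fell over all genes with edgeR, against 7 with the block within each line, 6 with DESeq2 and 2 with limma-voom, and 6 fell adjusted over the list alone. Col1a2, which codes for a chain of type I collagen, fell from 255.9 ± 140.3 to 1.22 ± 0.74 CPM (log2 -7.70, SE 0.779, adjusted p = 0.000557), beside Fbln2 and Fbln1 (log2 -4.92, SE 0.648, adjusted p = 0.00299). Col1a1, which codes for the other chain, was at 510.8 ± 250.4 against 1149 ± 612 CPM (log2 -1.17, adjusted p = 0.641). Among 24 p53 targets, 1 fell over all genes (2 with the block within each line, 3 with DESeq2, 1 with limma-voom) and 3 adjusted over the list alone. The gene that fell was Perp, a desmosome and apoptosis gene (log2 -4.29, SE 0.466, adjusted p = 0.000819), while Cdkn1a, which codes for the cell cycle inhibitor p21, was at 14.3 ± 11.8 against 14.4 ± 13.6 CPM. The p53 list was lost without knockout replicate 1 (camera adjusted p = 0.342), knockout replicate 2 (0.148) or put-back replicate 3 (0.586). With 1 library of the line left out its median ran from -0.49 to 0.0907, so its sign was not stable. The matrix median ran from -0.78 to -0.54.

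Of the remaining lists in the Fadd line, the 27 tested genes of retroelement silencing had a median of 0.0332, a mean of -0.159 and no call (adjusted p = 0.986), so median and mean differed in sign. Zcchc3, a cofactor of nucleic acid sensors, fell to 1 count over the knockout libraries from 0.546 ± 0.331 CPM, a ratio of 84.4 (14.7 to 3380; adjusted p = 0.00471). Suv39h1, a histone methyltransferase gene, fell by 0.89 (SE 0.173, adjusted p = 0.029), a call lost without any 1 of the 6 libraries (adjusted p from 0.0561 to 0.117), and Trim28, the corepressor of retroelements, was at 411 ± 106 against 401.6 ± 49.6 CPM. The cell cycle list had a median of -0.0878 over 30 genes (adjusted p = 0.185; 0.0422 without knockout replicate 2). The stress list (24 genes, -0.21, adjusted p = 0.185), the interferons and their receptors (8, 0.0937, 0.592) and the cell death list (25, 0.15, 0.92) gave no call. The marker lists of other cell types were thinly expressed. Epithelial markers had a median of -2.36 over 3 genes, of which Krt18 had no counts in this line, so that the value rests on Krt19 and Epcam (adjusted p = 0.0513), which became 0.0177 with the block within each line and 0.000724 without put-back replicate 3. Their adjusted p was 0.0422 and 0.047 without knockout replicate 1 or 2, and 0.048 without put-back replicate 2. Adjusted over the list alone, 2 members rose and 2 fell in the cell death list, 2 fell in the retroelement list and 2 fell among the epithelial markers (Krt19 and Epcam). Leukocyte (5 genes, -0.40, adjusted p = 0.841), endothelial (3, -0.0378, 0.92), muscle (4, -0.59, 0.597) and neural markers (7, median 0, mean -0.00142, ranked up, 0.92) gave no call.

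**Figure D2:**
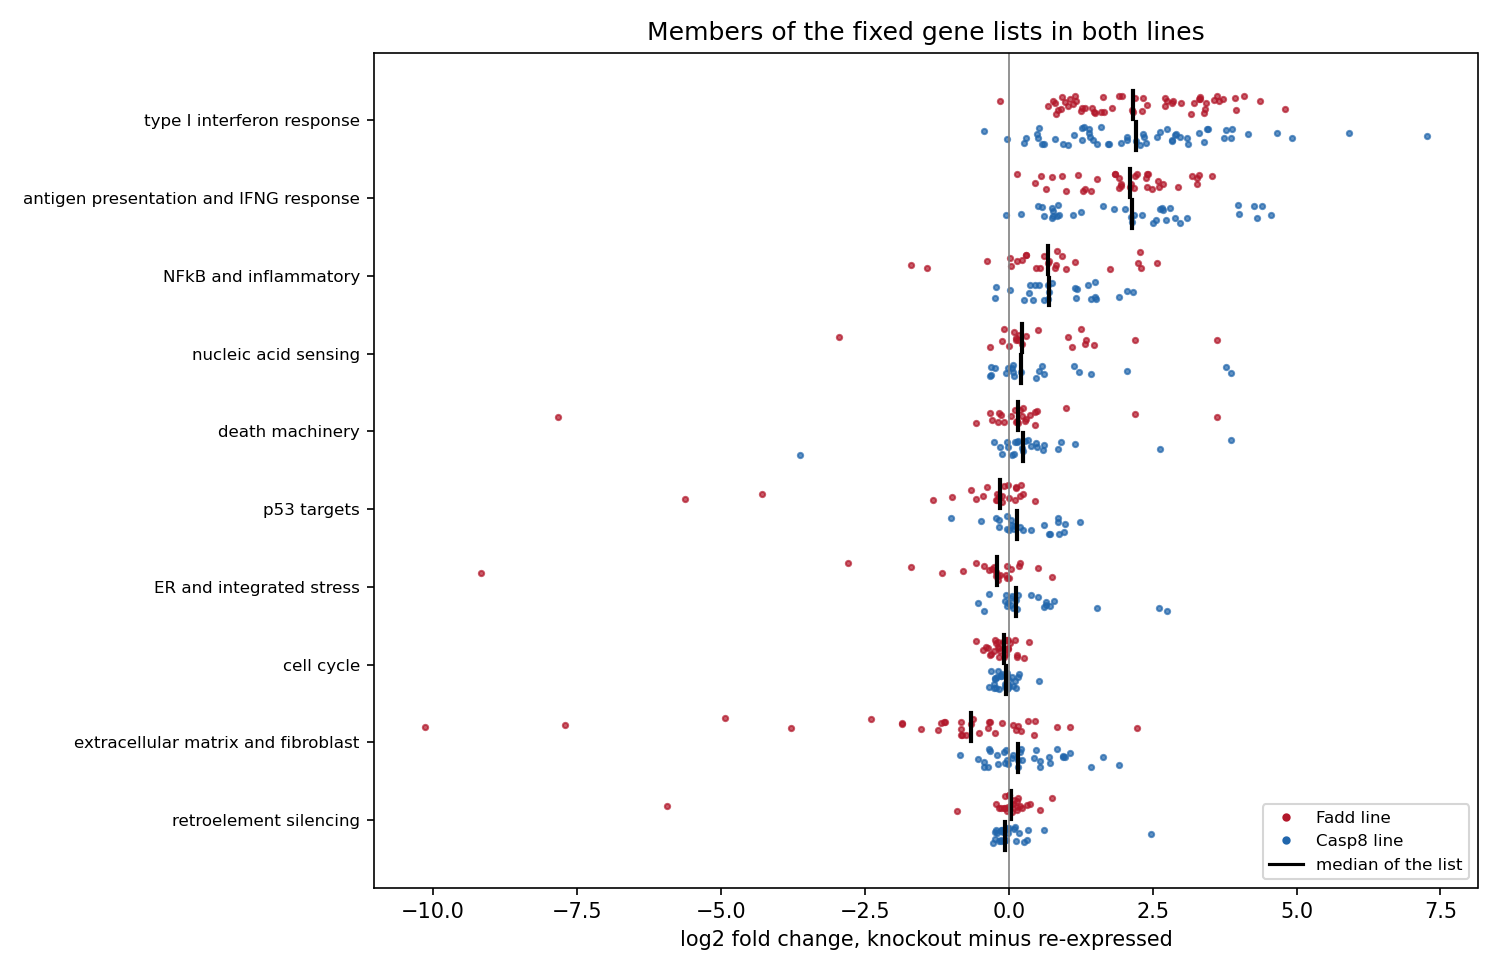
Log2 change of the tested members of 10 of the 16 fixed lists, without against with the protein, in the Fadd line and the Casp8 line. Each point is a gene and the black tick is the list's median. The type I interferon medians are 2.16 and 2.22, and the matrix medians -0.66 and 0.17.

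In the Casp8 line the single gene that passed was Casp8, and the interferon and antigen presentation lists had positive medians that were called with camera's preset correlation alone. Casp8 (ENSMUSG00000026029.14, chromosome 1, 58795374 to 58847503) fell from 140.6 ± 63.4 to 11.3 ± 1.0 CPM, a log2 change of -3.63 (SE 0.325, adjusted p = 0.00371). Put-back replicate 1 held 67.6 CPM of Casp8, against 172.1 and 182.2 in put-back replicates 2 and 3. In the Fadd line Casp8 stood at 43.1 ± 3.5 and 48.8 ± 5.1 CPM. By edgeR 0 genes rose and 1 fell, with 930 genes at an unadjusted p under 0.05, 675 of them higher, against 819.8 by chance. DESeq2 called 132 higher and 11 lower, and limma-voom 0 and 1. The Casp8 call was lost without knockout replicate 2 (adjusted p = 0.0707) and when only the 6 libraries of the line were fitted (0.28). The count was 3, 0 and 2 without knockout replicate 1, 2 or 3 and 22 without put-back replicate 1 (16 higher, 6 lower). Without both replicate 1 libraries, a setting chosen after seeing the data, it was 111 (99 higher, 12 lower). With the block within each line it was 6, where Hoxb9, Pax6, Grem1, Slco2a1 and Lamb1 rose beside the fall of Casp8. These 5 genes were named after their values were seen. On the first principal component the replicate 1 libraries of this line stood at 22.3 and 36.3, against 81.9 to 103 for its other libraries. Those of the Fadd line ranged from -113.9 to -38.3.

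Zbp1 was at 0.791 ± 0.456 CPM without caspase-8 and 0.0513 ± 0.0740 CPM with it, a log2 change of 3.87 (SE 1.4) that did not pass (edgeR adjusted p = 0.701). All 3 knockout libraries (0.300, 0.874 and 1.20 CPM) lay above the put-back libraries, which held 8 Zbp1 counts in all. The log2 change was 5.99 without put-back replicate 1 (adjusted p = 0.294). Ripk3, the kinase that acts on MLKL, stood at 57.4 ± 7.3 against 26.0 ± 13.4 CPM (log2 1.15, SE 0.355, adjusted p = 0.647), and Ripk1, Mlkl and Fadd had log2 changes of 0.16, 0.23 and 0.11. Apobec3, a restriction factor of retroviruses, was at 21.1 ± 2.0 against 3.79 ± 1.38 CPM, 2.48 higher on the log2 scale (SE 0.32). Its edgeR adjusted p was 0.0644, against 0.0295 without put-back replicate 1, 0.0118 with no count filter and 2.95e-10 with DESeq2.

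The type I interferon list had a median log2 change of 2.22 in the Casp8 line, with 53 of 55 members above 0. It ran from 1.79 to 2.65 with 1 library of the line left out and was 3.00 without both replicate 1 libraries, so the near-equal medians of both lines depend on these libraries. Over all genes 0 passed with edgeR, against 28 that rose adjusted over the list alone, 37 at an unadjusted p under 0.05, 14 with DESeq2 and 0 with limma-voom. Isg15 was at 15.3 ± 11.8 against 2.46 ± 0.54 CPM (log2 2.63, adjusted p = 0.617). The antigen presentation list had a median of 2.15 (1.87 to 2.49, and 2.90 without both) with 36 of 37 members above 0. Of these 0 passed over all genes, 22 rose adjusted over the list alone, 24 were at an unadjusted p under 0.05, 13 passed with DESeq2 and 0 with limma-voom. With the block within each line 0 members of either list passed. H2-K1 stood at 139 ± 43 against 28.1 ± 17.2 CPM (log2 2.31, adjusted p = 0.424), and Psmb8, an immunoproteasome subunit gene, at 9.55 ± 7.04 against 0.452 ± 0.415 CPM (log2 4.40, adjusted p = 0.37). The mean log2 CPM of the type I interferon list was 2.66 ± 1.15 without caspase-8 and 0.817 ± 0.491 with it (exact permutation p = 0.2, two-sided; 0.5 for an exact paired test). Knockout replicate 1, at 1.33, lay below put-back replicate 1, at 1.37. The Y-linked genes were also low in those 2 libraries, with Kdm5d at 7.19 and 19.8 CPM against 40.9 to 47.5 in the other 4 libraries of the line.

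Camera with the preset correlation called 7 lists in the Casp8 line, all higher without the protein, and 0 with an estimated correlation or fry. Type I interferon (adjusted p = 3.91e-40), antigen presentation (1.17e-35) and NF-kappaB (median 0.70, 7.24e-14) each had an adjusted p of 0.231 with an estimated correlation. In the NF-kappaB list 5 of 25 members rose adjusted over the list alone, and 0 over all genes (10 at an unadjusted p under 0.05; DESeq2 3; limma-voom 0). Nucleic acid sensing (median 0.22, 0.00215, estimated 0.468), interferons and receptors (0.14, 0.0363, estimated 0.541), cell death (0.24, 0.0366, estimated 0.33) and epithelial markers (1.06, 0.0487, estimated 0.231) were the other 4. The receptor and cell death lists were lost without knockout replicate 1 (adjusted p = 0.118 and 0.137), knockout replicate 2 (0.0752 and 0.0752), put-back replicate 1 (0.0991 and 0.473) or put-back replicate 3 (0.0856 and 0.0955). The epithelial list was lost without knockout replicate 1 (0.119) or put-back replicate 1 (0.163), and with DESeq2 size factors (0.0533). In the sensing list, which shares members with the type I interferon list, 2 of 21 members rose adjusted over the list alone. Matrix genes had a median of 0.17 (adjusted p = 0.495) that passed without knockout replicate 1 (7.53e-05), and p53 targets a median of 0.14 (0.103) that passed with the block within each line (0.0159), without knockout replicate 3 (0.0267) and without put-back replicate 2 (0.0449). The cell cycle list (median -0.0519, adjusted p = 0.127; 0.0466 without knockout replicate 1), the stress list (0.13, 0.284), and leukocyte (0.63, 0.479) and endothelial markers (0.30, 0.592) gave no call. Muscle markers (median -0.0377, ranked up, 0.92), neural markers (median -0.0391, mean 0.32, ranked down, 0.92) and retroelement silencing (median -0.0727, mean 0.0796, ranked up, 0.923) gave none either and differed in sign between measures. Adjusted over the list alone, Casp8 fell in the cell death list, Apobec3 rose in the retroelement list and Tubb3 rose among the neural markers.

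Genes that moved together in both lines were sought next, since the title names both proteins. At the adjusted threshold 0 genes changed the same way in both lines with edgeR, and 1 did without Casp8-line put-back replicate 1. DESeq2 gave 22, of which 21 were higher and 15 belong to the 2 interferon lists, among them Rsad2, Gbp5, H2-T23 and Iigp1. At an unadjusted p under 0.05, 140 genes were higher in both lines, where independent lists would share 29.7 (odds ratio 6.82, Fisher's exact p = 5.3e-57, two-sided). Of these, 49 are among the 92 tested genes of the interferon lists and 91 are not. The fixed lists are not complete, so this split reflects list membership. The 91 include the interferon-induced gene Ifi47, and Gbp10, H2-Q5 and H2-T10 of families with listed members, named after the values were seen. For lower levels 14 genes were shared against 14.95 (Fisher's exact p = 0.894). Across genes, the log2 changes of both lines had a Pearson r of 0.65 over the type I interferon list (52 of 55 with the same sign), 0.63 over antigen presentation genes (36 of 37) and 0.0146 over all 16396 genes, and genes are not independent replicates.

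**Figure D3:**
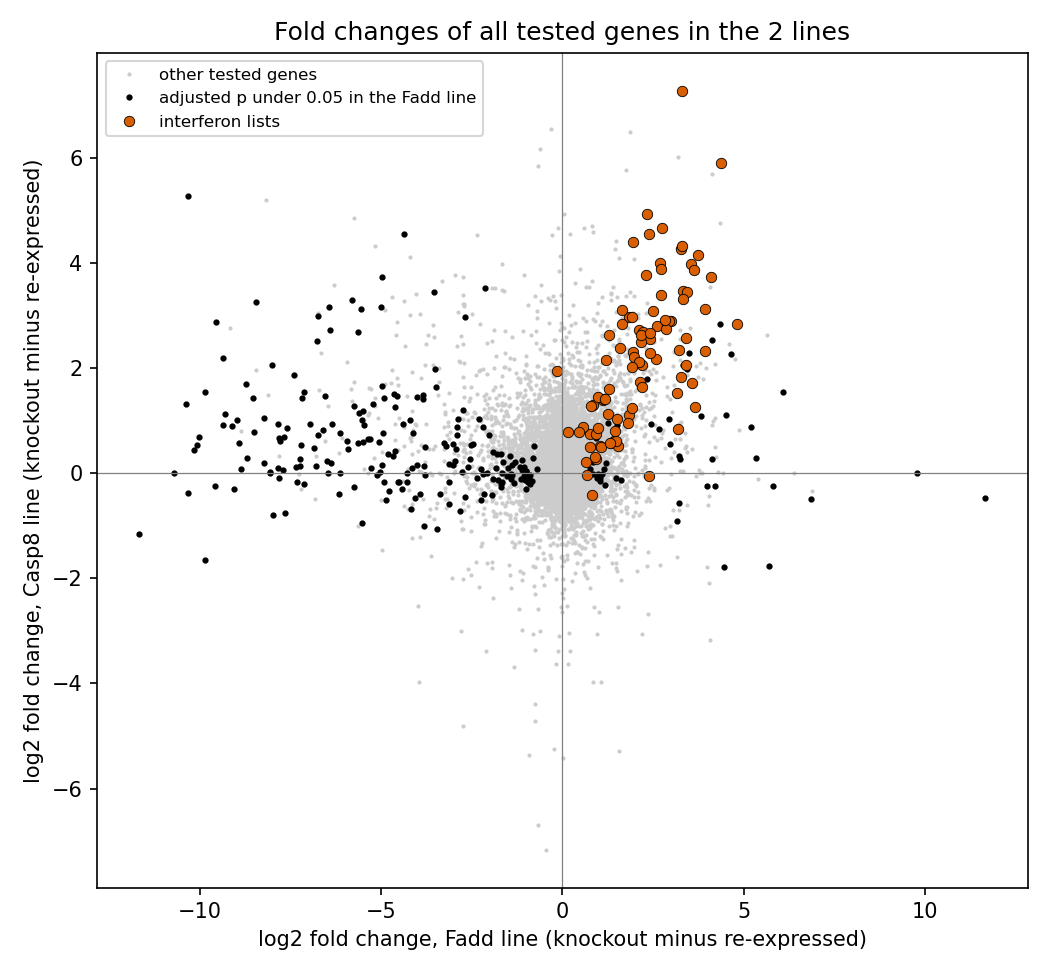
Log2 change without against with the protein for each tested gene, in the Fadd line (horizontal axis) and in the Casp8 line (vertical axis). Orange points are members of the 2 interferon lists, black points other genes with an adjusted p under 0.05 in the Fadd line, and grey points the rest. The orange points lie mostly at upper right, and the black points spread along the horizontal axis.

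The difference between the lines was tested for each gene, to find where the change without FADD was unlike the change without caspase-8. Line and missing protein go together in this design, so such a difference cannot be assigned to the protein alone. The change was more positive in the Fadd line for 9 genes and more negative for 129 (edgeR). The developmental genes Hoxc11 and Hoxa11 were among the 9, with differences of at least 9.03 for Hoxc11, at the floor of 3 counts over the group (adjusted p = 4.83e-05), and 3.79 for Hoxa11 (SE 0.31, adjusted p = 0.00021) on the log2 scale. Nlrx1, a mitochondrial regulator of innate immunity, differed by 2.87 (SE 0.488, adjusted p = 0.0176), a call lost without Fadd-line knockout replicate 2, put-back replicate 2 or 3, Casp8-line knockout replicate 3 or put-back replicate 2 or 3 (adjusted p from 0.0516 to 0.0727). Negr1 differed by 7.34 (SE 1.29, adjusted p = 0.0214), a call lost without Fadd-line replicate 1 or 2 of either group or Casp8-line knockout replicate 2 or 3 (0.0507 to 0.0846). Grem1, a BMP antagonist gene, differed by -12.43 (SE 1.5, adjusted p = 0.00255; 0.122 with limma-voom), from a fall in the Fadd line to 0.146 ± 0.167 from 105 ± 103 CPM and levels of 4.75 ± 0.91 against 0.643 ± 0.035 CPM in the Casp8 line. Gpx7 and Erfe had no reads in the Fadd/Mlkl knockout libraries, at least 46.5-fold and 87.5-fold below the put-back libraries. At that floor the differences were -8.80 and -8.64 or further from 0 (adjusted p = 0.00418 for each), taking the Casp8 line's change as fitted, as for Hoxc11. Cadm1 differed by -15.59 (SE 2.3, adjusted p = 0.00692), and by -7.26 (adjusted p = 1) without Casp8-line knockout replicate 1, the 1 knockout library of that line with Cadm1 reads. The count was 239 with the block within each line, 241 without Casp8-line knockout replicate 1 and 90 without Casp8-line put-back replicate 3.

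By camera, 3 lists differed between the lines. The matrix list was lower in the Fadd line by a median of -0.77 (adjusted p = 9.34e-08), the epithelial markers by -3.42 (0.00706, with Fadd-line counts for Krt19 and Epcam alone) and the p53 targets by -0.53 (0.00285), with adjusted p of 0.231, 0.231 and 0.457 with an estimated correlation. The p53 difference was lost without Fadd-line knockout replicate 1 (0.0561) or put-back replicate 3 (0.101). The type I interferon list (median 0.1, mean -0.024, adjusted p = 0.509) and the antigen presentation list (-0.18, 0.984) were not called. The first passed without Fadd-line knockout replicate 2 (0.0412) or 3 (0.0223) or Casp8-line knockout replicate 2 (0.0267), and the second without Fadd-line knockout replicate 1 (0.0111). Without both Fadd-line replicate 1 libraries their medians were -1.10 and -1.11 (4.27e-06 and 9.1e-06), and without both Casp8-line replicate 1 libraries -0.71 and -0.90 (0.0352 and 0.0103), where the epithelial difference was lost (0.107). These 2 settings were chosen after seeing the data. The stress list (-0.21, 0.0662) passed without Fadd-line knockout replicate 2 (0.0422) or 3 (0.0373), put-back replicate 3 (0.0295), Casp8-line knockout replicate 1 (0.0245) or 3 (0.0426) or put-back replicate 1 (0.0273). The other 10 lists were not called, with adjusted p from 0.204 to 0.92. Of these, nucleic acid sensing (median 0.13, mean -0.159), neural markers (0.0576, mean -0.325) and retroelement silencing (0.11, mean -0.238) differed in sign between median and mean.

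The knockout cultures of the 2 lines were also set against each other. Line of origin and missing gene cannot be separated in this comparison alone. By edgeR 568 genes were higher in the Fadd/Mlkl knockout and 1150 lower, 1420 of them at least 2-fold. Among the higher genes were Mapt, which codes for the protein tau (23.9 ± 15.6 against 0.037 ± 0.046 CPM; log2 9.36, SE 1.35, adjusted p = 0.00145), Klhl38 (1 count over the Casp8/Mlkl knockout libraries, a ratio of 866 with an interval of 155 to 34300, adjusted p = 0.00293), and Oas3 (71.5 ± 79.6 against 0.152 ± 0.072 CPM; log2 8.82, SE 1.29, adjusted p = 0.00334). Lower were the collagen-related gene Cthrc1, the lipoprotein receptor gene Vldlr and the Y-linked histone demethylase gene Kdm5d, none with reads in the Fadd/Mlkl knockout. They were at least 4610-fold, 1900-fold and 1610-fold lower, with adjusted p of 0.00125 (0.0534 with limma-voom), 0.00698 (0.108 with limma-voom) and 0.00148. Kdm5d had no counts with Fadd put back either, so its absence goes with the line and not with the state of FADD. The count of 1718 became 1074 and 1119 without Fadd/Mlkl knockout replicate 1 or 3, and 829 and 866 without Casp8/Mlkl knockout replicate 2 or 3. Fitted on these 6 libraries alone it was 1046.

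Counts over annotated endogenous retrovirus open reading frames were deposited as well, in 60983 annotated regions of which 16726 had a count in any library and 504 could be tested. Their total, as CPM of the gene counts, was 1198 ± 169 without FADD and 1059 ± 31 with it (exact permutation p = 0.2, two-sided, where 0.1 is the smallest possible). All 3 pairs of the same replicate number were higher without FADD, by 32.9 to 297 (exact paired permutation p = 0.25, the smallest for 3 pairs). With effective library sizes it was 1173 ± 141 against 1023 ± 8.37, with all 3 knockout libraries above (exact permutation p = 0.1), and without the 10 most abundant regions 560.3 ± 132 against 530 ± 71.9 (exact permutation p = 0.8; 2 of 3 pairs higher). In the Casp8 line the total was 1202 ± 373 without caspase-8 and 1027 ± 126 with it (exact permutation p = 0.7, 0.7 and 0.9 in the 3 scalings), with 2 of 3 pairs higher, where the ratio reversed in sign, to -0.0443 on the log2 scale, without knockout replicate 3. The 10 most abundant regions held 48.1% of the counts. In the Fadd line 0 regions rose and 3 fell with edgeR, 44 were at an unadjusted p under 0.05 against 25.2 by chance, and DESeq2 called 15. Adjacent regions on chromosome 7, 48126559 to 48129195 and 48129938 to 48131425, had no counts in the 3 knockout libraries, against 8, 15.5 and 11 counts and 7, 14.5 and 15.5 counts with Fadd put back (adjusted p = 0.0142 for each). A region on chromosome 16, 3630789 to 3631760, had 1.5, 4 and 4 counts against 27, 27.5 and 27 (log2 -3.20, SE 0.6, adjusted p = 0.0142). All 3 lie on the minus strand in no annotated gene of that strand, and were named after their values were seen, since they lie below the count minimum set for named regions.

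The count of changed regions in the Fadd line was 17 with the replicate number as a block (3 higher, 14 lower) and 22 with the block within each line (7 higher, 15 lower). It was 8 without knockout replicate 2 and 0 without knockout replicate 1 or 3 or put-back replicate 2 or 3. In the Casp8 line 0 regions passed with edgeR, 28 were at an unadjusted p under 0.05 and DESeq2 called 1. In simulated data, 2-fold changes of regions were recovered for 8% in the Fadd line and 12% in the Casp8 line. For 4-fold changes the shares were 60% and 44%, so few calls do not show that regions were unchanged. There were 2 without knockout replicate 1. The median log2 change of the tested regions was 0.0267 in the Fadd line and 0.36 in the Casp8 line. Which family each region belongs to, and how reads that map to many places were counted, is not given in the sources used here.

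**Figure D4:**
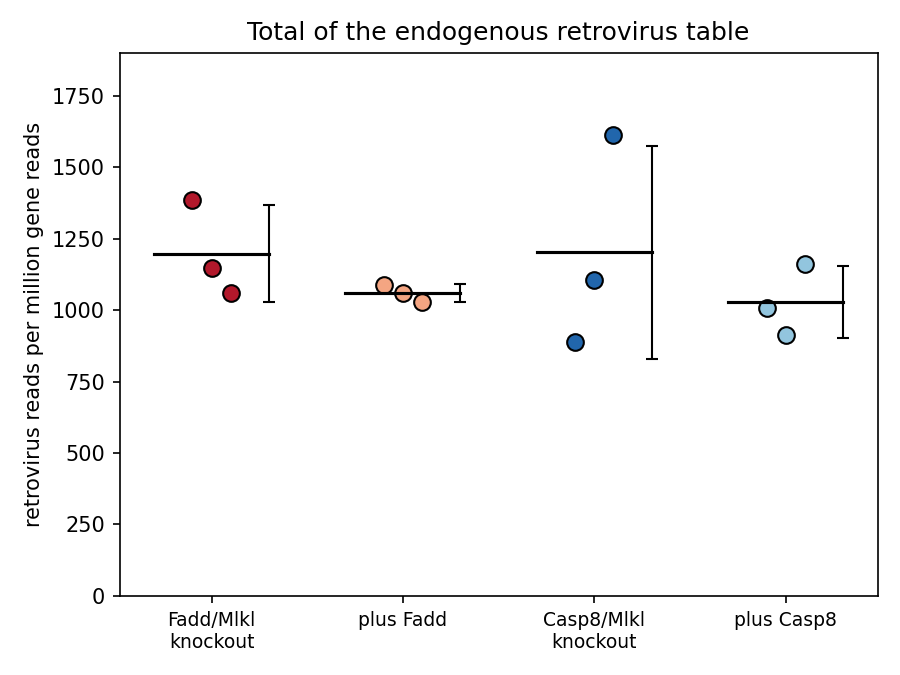
Total counts over annotated endogenous retrovirus regions as CPM of the gene counts, for each library in the 4 groups, on an axis that starts at 0. Points are libraries, lines are group means and bars are 1 SD. Means lie between 1027 and 1202, with the highest library, at 1614, in the Casp8/Mlkl knockout.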

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

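The test on the neighbours of silent genes, both tests of Fadd-line cells on gene sets, and the counts over other splits were set before their results were seen, while the count over all splits that part every pair in both lines and the tests of a shared response, of culture divergence, of Casp8 transcripts, of Y chromosome loss, of a batch, of swapped labels and of immune cells were chosen only afterwards.

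For 18 named genes the change without the protein differed between the Fadd line and the Casp8 line by edgeR's test of the difference. On the log2 scale, Fadd line minus Casp8 line, the missing genes themselves differed by -7.94 for Fadd (SE 0.524, adjusted p = 4.83e-05) and 3.45 for Casp8 (SE 0.426, adjusted p = 0.00283). The difference was positive for Hoxc11 (12.13), Negr1 (7.34), Hoxa11 (3.79) and Nlrx1 (2.87). It was negative for Cadm1 (-15.59), Grem1 (-12.43), Gpx7 (-11.70), Erfe (-11.53), Zfp422 (-10.72), Enpp5 (-10.69), Fbln2 (-10.59) and Gas6 (-10.49). Without Casp8-line knockout replicate 1, the only knockout library of that line with Cadm1 reads, Cadm1 was at -7.26 (adjusted p = 1). Leaving out 1 library lost Negr1 and Nlrx1 in 6 of 12 fits each, and limma-voom lost Cadm1 (adjusted p = 0.0671), Grem1 (0.122) and Negr1 (0.055). The difference was also negative for Col1a2 (-7.76, SE 0.924), Zcchc3 (-6.555, SE 1.07), Fbln1 (-6.35, SE 0.839) and Perp (-4.115, SE 0.599). Hoxc11, Gas6, Gpx7 and Erfe have a group with no counts, so their fitted values are no measured size. At a floor of 3 counts over that group, with the Casp8 line's change as fitted, they were 9.03, -7.65, -8.80 and -8.64 or further from 0. By camera, with a preset correlation, the epithelial markers (-3.42, adjusted p = 0.00706), matrix genes (-0.77, adjusted p = 9.34e-08) and p53 targets (-0.53, adjusted p = 0.00285) differed as lists. With an estimated correlation their adjusted p were 0.231, 0.231 and 0.457, and of the 3 epithelial markers Krt18 had no counts in the Fadd line.

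Within a line, 3 libraries against 3 give 10 splits, too few for a share under 0.05. In the Fadd line the real split gave 250 genes, 6 lists and 3 retrovirus regions, and the highest of the other splits 0 genes, 9 lists and 0 regions. In the Casp8 line the real split gave 1 gene, 7 lists and 0 regions, and the highest other 9 genes, 5 lists and 0 regions. The split with 9 genes exchanges both replicate 1 libraries. Since replicate numbers pair the libraries, the 3 other splits that part every pair are the closest match, and each exchanges the libraries of 1 pair. They gave 0, 0 and 0 genes and 8, 7 and 4 lists in the Fadd line, and 0, 0 and 9 genes and 3, 1 and 5 lists in the Casp8 line. Between the knockout groups the real split gave 1718 genes and the highest other 0. For the difference between the lines, 4 of 100 splits drawn without regard to the pairs gave at least the 138 genes of the real one. Among all 32 splits that part every pair in both lines 2 did, with 200 in the highest other, so chance cannot be excluded where the pairs are kept. Those of the 32 that keep knockout and put-back libraries of the Fadd line apart, as labelled or with the 2 labels exchanged, gave 52 to 200 genes. All others gave 0, whatever the grouping of the Casp8 line. The highest other of the 100 gave 1148, which points to a structure among the libraries. That split and the other 2 with more genes than the real one (200 and 166) part knockout replicate 1 of the Casp8 line from replicates 2 and 3 of its group. The split with 1148 also mixes the groups of the Fadd line. The other 2 keep those groups apart but exchange their labels. With a block within each line the count was 239. For genes changed the same way in both lines (0 with edgeR, 140 higher and 14 lower at an unadjusted p under 0.05 in each line, 22 with DESeq2), every split gives as many as a real count of 0 (100 of 100, highest other 1), so this count says nothing about chance.

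The first pattern is a set of 116 genes at least 16-fold lower without FADD, against 15 genes at least 16-fold higher, with a median log2 change of -6.48, or -5.85 with the 28 genes without counts at their bound. Loss of a chromosome segment is argued against, since tested neighbours on both sides had a median change of -0.138 (95% interval -0.23 to -0.0807), and the genes lie on 21 chromosomes with at most 12 on any. A response shared by the loss of either protein is argued against for the set, whose median change in the Casp8 line was 0.62 (0.43 to 0.78). Both intervals come from resampling the genes, so they measure spread among genes and not between cultures. Of the 116 genes 84 differed between the lines. That count is no independent support, since the genes were chosen for their Fadd-line change, which is part of the difference. Divergence of the cultures apart from FADD stays open, as 64 of the 116 genes had at most 3 counts over the knockout libraries and 86 reached 1 CPM in the Casp8/Mlkl knockout. The labels describe no second derivation of either culture, so this and an effect of FADD itself, which was not tested apart, cannot be told apart.

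The second pattern is the low level of 4 Y-linked genes in replicate 1 of the Casp8 line, at 16.3 to 31.5% of replicates 2 and 3 in the knockout and 39.6 to 49.7% with Casp8 put back, where autosomal medians were 100.2 and 95.98%; the test first took 9 Y-annotated genes, and the 5 left out afterwards, which had up to 119 CPM in the Fadd line, stood at 47.8 to 170%. Loss of the Y chromosome in part of the cells gives the 49.7% seen at most, but not the level of 16 autosomal genes silent in the Fadd line, which was 3.57% (95% interval 0.897 to 11) in knockout replicate 1 and 15.4% (6.93 to 50.3) in the other. Those levels met what had been set beforehand for Fadd-line cells as the whole of the loss, yet 3.57% lies below the Y-linked genes of the same library, and the Casp8 transcripts of that library, at 12.4 CPM against 11.3 and 10.4 in the other knockout libraries and 39.3 to 54.5 in the Fadd line, allow 5.44% of such cells (up to 6.96%), which argues against it there. A smaller admixture stays open, since 13 genes of the Fadd line reached 14.4% (1.51 to 41) of their level in knockout replicate 1 and 1.81% (0.9 to 3.8) in the put-back library. The transcript test was set for the knockout library alone, since Casp8 also comes from the vector in the put-back library. Casp8 in put-back replicate 1 stood at 67.6 CPM, against 172.1 and 182.2 in put-back replicates 2 and 3. The cause of this shortfall was not tested. The intervals for these gene sets come from resampling genes and do not measure spread between cultures. A part of the Casp8-deficient cells in another state was not tested, and no group of the design gives a biological explanation.

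The third pattern is the spread of interferon genes within groups, where the mean log2 CPM of the type I list ran from 5.27 to 7.09 in the Fadd/Mlkl knockout and from 1.33 to 3.42 in the Casp8/Mlkl knockout. A batch moving these genes the same way in all replicate 1 libraries is argued against. Replicate 1 was highest in 2 of the 4 groups and lowest in the other 2. A batch acting unlike in the groups stays open, since this test cannot detect it. Libraries with the same replicate number did deviate together within each line. Swapped labels of the replicate 1 libraries of the Casp8 line are argued against by 12.4 CPM of Casp8 in the library called knockout, close to the other knockout libraries (at most 11.3) and far from its partner at 67.6. Immune cells are argued against by 0.0527 CPM (95% limit 0.154) for the highest of Ptprc, Tyrobp, Laptm5 and Fcer1g in the library with the most interferon response. What differed between cultures of 1 group is not in the labels, more interferon made in the highest library (0.896 CPM of interferon transcripts, taken up under the observations) was the biological explanation tested, for that library alone, and a difference in RNA make-up stays open as untested, since the highest library had 81.4% of its counts in protein-coding genes against 85.0 to 88.8% in the others.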

How the results depend on the processing

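The block within each line and the fits without both replicate 1 libraries of a line were chosen after seeing the data, and all other alternatives before. With DESeq2 size factors in edgeR, a 1 CPM filter, limma-voom and a change of at least 2-fold, every count of genes stayed within 1.5 times its value, and Zbp1 passed under none of the alternatives run (adjusted p from 0.0634 to 0.806 in the Fadd line and 0.166 to 1 in the Casp8 line).

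With DESeq2 the counts were 697 in the Fadd line, 143 in the Casp8 line, 420 for the difference, 2753 between the knockout groups and 22 changed the same way in both lines, and 15 and 1 retrovirus regions in the Fadd and Casp8 line. With no count filter 4 genes and 2 regions passed in the Casp8 line and 13 regions in the Fadd line, and with the retrovirus table's own scaling 7 regions in the Fadd line. Fitted on the compared libraries alone, 0 genes passed in the Casp8 line (930 at an unadjusted p under 0.05 in the fit to all libraries, 143 with DESeq2) and 1046 between the knockout groups, a setting with fewer libraries. An estimated correlation or fry left 0 lists in each line. The planned replicate block gave 17 regions in the Fadd line, moved the cell death list in the Casp8 line (adjusted p = 0.0758) and Relb and Suv39h1 in the Fadd line out of their calls and the epithelial markers in the Fadd line into one (0.0204 by camera), and changed no other call of a named gene or list, with 265 genes in the Fadd line, 144 for the difference and 2050 between the knockout groups. Within each line, the block gave 444 and 6 genes, 239 for the difference and 22 regions in the Fadd line, and changed 3 list calls (nucleic acid sensing and epithelial markers in the Fadd line, p53 targets in the Casp8 line). Without both replicate 1 libraries, the Casp8 line gave 111 genes (99 higher, 4 of them in the interferon lists), 391 for the difference and 4 regions, while the Fadd line gave 111 genes and 0 regions. In the first setting the Casp8 line lost nucleic acid sensing (camera adjusted p = 0.0692), cell death (0.292), receptors (0.126) and epithelial markers (0.412) and gained stress and matrix genes (0.0103 each), and the difference lost epithelial markers (0.107) and gained stress (0.00293), type I interferon (0.0352) and antigen presentation (0.0103). In the second the Fadd line lost nucleic acid sensing (0.559), the Casp8 line epithelial markers (0.0515), and the difference gained type I interferon (4.27e-06), antigen presentation (9.1e-06), cell death (0.0244) and NF-kappaB (0.0391). The cause of these shifts was not tested.

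Leaving out each library in turn, counts ran from 103 to 181 genes in the Fadd line, 0 to 22 in the Casp8 line, 90 to 241 for the difference, 829 to 2558 between the knockout groups and 0 to 1 changed the same way in both lines. Lists ran from 5 to 7 and 4 to 8, and regions from 0 to 8 and 0 to 2. Zbp1 ran from 2.12 to 4.23 in the Fadd line and 3.33 to 5.99 in the Casp8 line on the log2 scale. The total of retrovirus regions in the Casp8 line ran from -0.0443 to 0.404, the lowest without knockout replicate 3, and in the Fadd line from 0.0592 to 0.258.

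Of the values for named genes under the alternatives, 1249 kept direction and side of the threshold, 62 lost their call, 24 gained one and 18 changed sign, all of them values that did not pass. In the Fadd line Cdkn1a (-0.0131) was 0.0156 with a 1 CPM filter, 0.17 with the replicate block and -0.82 to 1.12 with libraries left out. Col3a1 (-0.51) ran from -0.93 to 0.17, Mlkl (-0.32) from -0.63 to 0.13 and Trim28 (0.0332) from -0.16 to 0.21. In the Casp8 line Col1a1 (0.16) was -0.12 with limma-voom, -0.0509 with the block within the line and -0.26 to 0.61 with libraries left out. Col3a1 (0.55) was -0.42, -0.26 and -0.0701 to 1.10, and Trim28 (-0.0975) ran from -0.25 to 0.0233. Each of these changes was smaller than its standard error over all libraries, and the cause of the reversals was not tested. Depth limits genes near the floor, where a group held 3 counts or fewer.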

Other observations

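Both hypotheses tested in this part were written down before their results were seen, while the Hox genes, Unc93b1, the block within each line and the fit without both replicate 1 libraries were chosen after values were seen.

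Besides Hoxc11, 2 of the 30 Hox genes tested, which set position along the body axis, rose in the Fadd line with edgeR, and the other 27 did not pass. Hoxa11 stood at 25.03 CPM against 2.68 CPM with Fadd put back (log2 3.22, SE 0.232, adjusted p = 5.78e-05) and Hoxa13 at 0.708 against 0.109 CPM (log2 2.66, SE 0.584, adjusted p = 0.0498). The HoxB cluster differed between libraries of the Casp8 line. Its 9 tested genes had a median log2 change of 3.84 without caspase-8, or 3.73 with Hoxb5, which had no counts with Casp8 put back, at its bound. The smallest edgeR adjusted p among them was 0.639. Without both replicate 1 libraries it was 0.0803 while the median fell to 1.09, a fitted value near the floor of counts. With the block within each line Hoxb9 passed (log2 4.43, SE 0.365, adjusted p = 0.0343). The mean log2 CPM of the cluster was 1.496 in knockout replicate 1, against -3.32 and -3.66 in replicates 2 and 3, and -2.35, -4.31 and -3.66 with Casp8 put back, so that 1 library carries most of the change. It is 1 of the 2 libraries with low Y-linked genes, in which a smaller admixture of Fadd-line cells was left open. HoxB means in the Fadd line were 2.66 and 2.96. The Casp8 transcripts of knockout replicate 1 allow 5.44% of Fadd-line cells (up to 6.96%). That is too few for a HoxB mean of 1.496, which argues against Fadd-line cells as the whole of it. The Casp8 transcripts cannot limit other cells with little Casp8, which were not tested. In the Fadd line the median was -0.29.

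Unc93b1, which carries nucleic acid sensing Toll-like receptors to endosomes, went opposite ways. It was at 0.281 against 2.22 CPM in the Fadd line (log2 -2.96, SE 0.738, adjusted p = 0.0907) and at 3.10 against 0.226 CPM in the Casp8 line (log2 3.78, SE 0.767, adjusted p = 0.261). The difference of -6.73 passed (SE 1.06, edgeR adjusted p = 0.0106).

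Reads of interferon genes themselves were few. Reads were summed over interferon alpha, beta, epsilon, kappa, zeta and lambda genes. Knockout replicate 1 of the Fadd line, the library with the highest interferon response, held 51 such reads, 35 of them from Ifnb1. That is 0.896 CPM (95% Poisson interval 0.667 to 1.18, which covers counting error alone). Every other library had at most 13 such reads and 0.285 CPM (0.152 to 0.487), and at most 2 from Ifnb1. A candidate explanation for the height of the response in that library is therefore more interferon made in that culture. This rests on 1 library, and interferon protein was not measured. The same library also stood apart in RNA make-up, with the lowest protein-coding share (81.4% against 85.0 to 88.8%), and the highest shares of miscellaneous RNA (11.04% against at most 7.79%), mitochondrial ribosomal RNA (1.00% against at most 0.748%) and ribosomal RNA (0.108% against at most 0.0227%), and whether this goes with the interferon response was not tested.

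Endogenous retrovirus regions that lie within genes moved with those genes. Over 206 regions in a tested gene of the same strand, Spearman's rho between the log2 changes of region and gene in the Fadd line was 0.665 (95% interval 0.559 to 0.749), across regions that are not independent replicates. Reads of the host gene may therefore account for part of the changes of such regions. The 3 regions called in the Fadd line lie in no gene of the same strand, so this does not reach them.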
